A study of Canis lupus familiaris with 12 samples.

How the data were processed

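Total RNA from 4 cultured canine bone marrow stromal lines was measured on an Affymetrix canine expression array, with 3 biological replicates per line per the labels. Per the labels' protocols, cells were grown for a few days in RPMI medium with fetal serum until most of the plate was covered, and were lysed in the plate or after trypsin. Total RNA was purified on columns, and biotin-labelled complementary RNA was made from it. Which arrays were lysed in which way, the hybridisation dates and the donors are not given in the sources used here. The deposited table holds 1 intensity per probe set and array as whole numbers on a linear scale. The submitters' processing notes name GCRMA, a background correction, quantile normalization and summary method for Affymetrix probes, and its version and any later scaling are not given in the sources used here. The arrays were not reprocessed from scanner files. GCRMA pulls dim probe sets to a narrow low range, and whole-number rounding leaves equal values there, so small standard deviations of dim probe sets partly reflect rounding.

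The table held 43035 probe sets, of which 111 control probe sets were left out of the tests and 42924 were tested. No per-sample column was left unused. Gene symbols came from the platform annotation table: 29254 probe sets had 1 symbol (15115 distinct symbols), 439 had several and were not named, and 13231 had none there. Of the probe sets with 1 symbol, 27680 were matched by Entrez identifier to a current gene table, and 0 changed. No genome coordinates are given because the build behind the annotation is not given in the sources used here. Probe sets whose names end in _s_at or _x_at can match several transcripts, so genes measured by them are less certain. Pairs of arrays with identical values numbered 0. The 3 arrays of a line were treated as independent replicates, as their labels state.

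Intensities were converted to log2 and fitted with limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes over all 12 arrays, 1 mean per line and no covariate. A moderated F test asked whether a probe set differed among the lines, and moderated tests compared the 6 pairs. P-values were adjusted by the Benjamini-Hochberg method within each test. A probe set was called at an adjusted p under 0.05 with a log2 difference of at least 1, a fold of 2, or for the F test a range of line means of at least 1. A probe set was set apart in a line when it was called in the same direction against each of the other 3 lines, and 370 probe sets were set apart in more than 1 line. The size given for such a gene is its smallest difference to another line, with its largest adjusted p. Controls and array-level values were compared with two-sided exact permutation tests, whose smallest p is 0.1 for 3 arrays against 3.

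These lists, tests, thresholds and the naming rule were fixed before the data were examined. Named for each line were the 12 genes per direction with the largest smallest difference, among probe sets set apart with 1 symbol, with a mean of at least 6 on the log2 scale on the higher side and with all 3 arrays of the line beyond all 9 others. For each pair, 4 genes per direction were named by the same kind of rule, leaving out genes already named for a line. List members set apart in a line could be named, and in the surface marker, support factor, osteoblast, adipocyte and cartilage lists any member. Where the probe sets of a gene disagree, the number called is given for many genes but not for all. A gene named without it may still rest on part of its probe sets. The background was taken from 42 control probe sets for sequences foreign to the dog, with values of 3 to 27. There were 31 gene lists: mesenchymal stromal surface, leukocyte and haematopoietic, endothelial, smooth muscle and pericyte, skeletal muscle, epithelial, and neural and glial markers; osteoblast, adipocyte and cartilage genes; haematopoietic support factors, inflammatory cytokines, immune modulation, interferon response and antigen presentation; cell cycle, p53 targets, and cyclin-dependent kinase inhibitors with the RB family; collagens and matrix proteins, matrix proteases, insulin-like growth factor, Wnt, HOX, and limb patterning genes; cholesterol synthesis, glycolysis and hypoxia, antioxidant, immediate early, endoplasmic reticulum stress and DNA repair genes; and sex-linked genes, of which 0 were measured under their symbols, below the smallest list size of 5. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, on the brightest probe set of each gene, for each line against the mean of the other 3, and adjusted over the 120 tests.

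The steps were tested on simulated data in which line 3 differed from the other lines by known amounts over 42924 probe sets. Of 50 probe sets per size, 94% were recovered at 2.83-fold and 100% at 4-fold, 8-fold and 16-fold, with 0 false calls. The changed probe sets were drawn from those with a mean of at least 6 (log2) over all arrays, so recovery of dim ones was not tested. No difference in control level was simulated either. For the list step, a shift of 0.5 (log2) added to 1 list in line 2 gave an adjusted p of 4.44e-49 over 15115 genes. Tests of the other lists gave 0 calls. The simulated genes varied independently, so this cannot show how often lists of correlated genes pass. Alternatives tried were centring each array on its median, normalizing all arrays again to a single distribution, filters at line means of 5 and 7, a floor of 4, a trend and robust spread model, array weights, a replicate block, other thresholds, leaving out probe sets with _s_at or _x_at names, 1 probe set or the mean of all probe sets per gene, pairs fitted alone, the rotation test fry, an estimated correlation, and leaving out each of the 12 arrays. After seeing the control split, the F test and list test were also run on the contrasts of line 2 with line 1 and line 4 with line 3 alone.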

Results

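Gene expression was measured in 4 cloned stromal cell lines grown from dog bone marrow. The cells had been immortalised with a retrovirus carrying the E6 and E7 genes of a human papillomavirus, whose proteins inactivate p53 and the retinoblastoma protein, and clones resistant to the antibiotic G418 had been picked. The lines are called line 1 to line 4 here, and the labels do not say from how many dogs they came. Per the series text, the lines were meant for transplantation research in the dog, as a counterpart to human stromal lines, with graft-versus-host disease and radiation injury as the clinical problems. Each line was represented by 3 arrays labelled as biological replicates, which gave 12 arrays, and their number limits the precision. No untransformed or control cells were among the samples, so each line was compared with the others.

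The deposited values were whole-number intensities from 1 to 145258. The median intensity was 70, 70 and 69 on the arrays of line 1, 71, 72 and 71 in line 2, 71, 72 and 70 in line 3, and 71, 70 and 70 in line 4. The values behaved as a linear scale and were converted to log2, but any centring or scaling applied after the submitters' normalization stayed unknown. The 42 background control probe sets reached at most 27, or 4.75 on the log2 scale, and a mean at or under that level is called near background below. For a gene this refers to the probe set quoted, and another probe set of the gene can read higher. Of the 42924 tested probe sets, 15622 (36.4%) were near background in every line. A fold against a line near background depends on that background level. The median standard deviation between the arrays of a line was 0.10, 0.08, 0.10 and 0.11 (log2, n = 3 each) in lines 1 to 4. Pearson's r across probe sets, which are not independent replicates, was 0.996 to 0.998 between arrays of the same line and 0.956 to 0.984 between arrays of different lines.

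The control probe sets separated the arrays of lines 1 and 2 from those of lines 3 and 4. Bacterial and phage transcripts are added to each sample or hybridisation mix in fixed amounts as controls. The bioB controls were 5.34-fold brighter in lines 3 and 4 than in lines 1 and 2, bioC 4.21-fold, bioD 3.17-fold and cre 2.06-fold. A canine beta-actin control gave a signal at the 3' end of the transcript that exceeded the 5' end by 5.13 ± 0.31 in line 1, 4.51 ± 0.18 in line 2, 1.03 ± 0.09 in line 3 and 1.45 ± 0.29 in line 4 (log2, SD, n = 3). The canine GAPDH control did not show this gap, at 2.97, 2.81, 2.73 and 2.45 in lines 1 to 4. The background controls averaged 2.67 and 2.57 in lines 1 and 2 and 2.96 and 2.82 in lines 3 and 4 on the log2 scale. For bioB, each comparison of line 3 or line 4 with line 1 or line 2 gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 arrays against 3 allow. No line had arrays at both control levels. In the comparisons of line 1 or 2 with line 3 or 4, batch and group cannot be told apart, while lines 1 and 2, and lines 3 and 4, could be compared within a control level. The lines of a level still differed in other array-level values. The largest intensity, the background control mean and the canine beta-actin and GAPDH 3' minus 5' signals separated both pairs, each with exact permutation p = 0.1. A processing difference between the lines of a level is therefore not excluded.

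**Figure D1:**
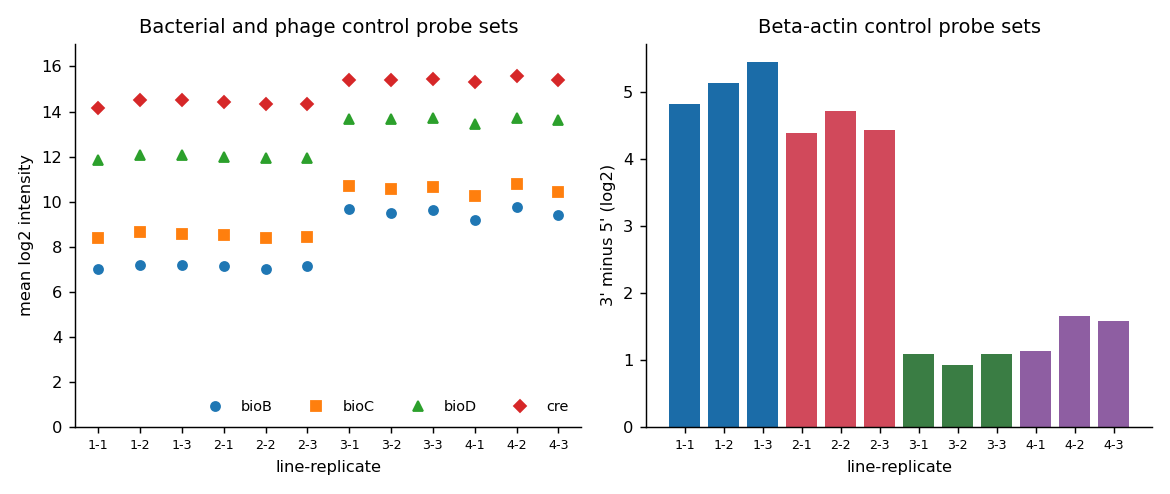
Left: mean log2 intensity (vertical axis) of the bioB, bioC, bioD and cre control probe sets on each of the 12 arrays (horizontal axis, line and replicate). Right: 3' minus 5' log2 signal of the canine beta-actin control on each array, with bars coloured by line; the line means were 5.13, 4.51, 1.03 and 1.45.

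Across the 4 lines, thrombospondin 2 (THBS2), a secreted matrix glycoprotein, read 13.38 ± 0.07 in line 2 and 14.17 ± 0.02 in line 3 (log2 mean ± SD, n = 3) but 2.32 and 2.41 in lines 1 and 4, a 3688-fold range. The neuronal ubiquitin hydrolase UCHL1 spanned 614-fold, the messenger RNA binding protein IGF2BP1 288-fold, and INSIG1, which retains the activator of sterol synthesis in the endoplasmic reticulum, 116-fold. All 17 measured cholesterol synthesis genes and 25 of 31 collagen and matrix genes differed among the lines. In limma's F test, 12824 of 42924 probe sets (29.9%), with 6110 named genes, passed an adjusted p of 0.05 with a range of line means of at least 1 on the log2 scale. The F test restricted to the contrasts within a control level, chosen after seeing the data, called 5305 probe sets.

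**Figure D2:**
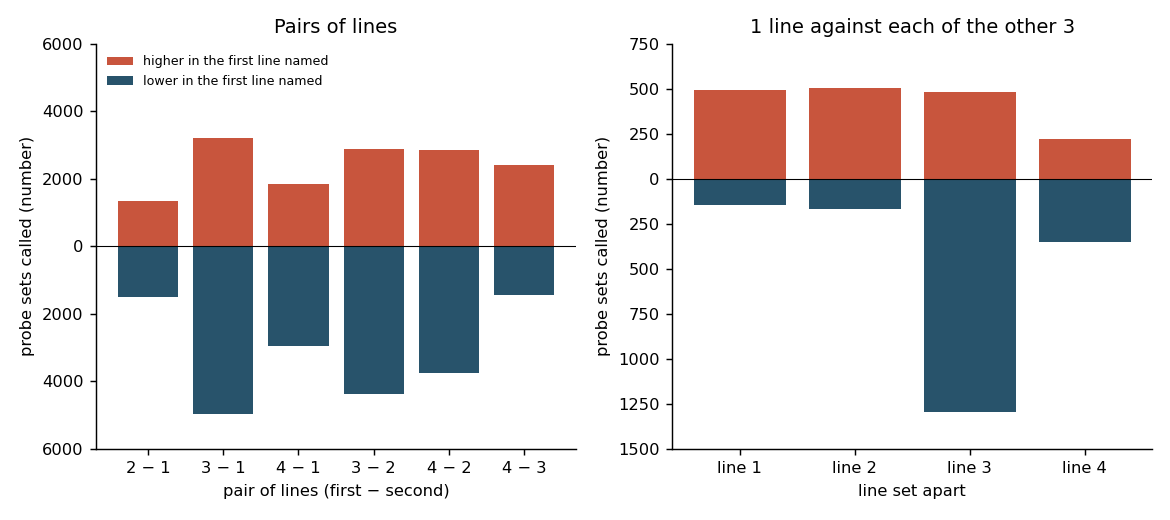
Left: number of probe sets called (vertical axis) in each of the 6 pairs of lines, with bars above 0 for probe sets higher in the first line named and bars below 0 for lower ones. Right: number called higher (up) or lower (down) in 1 line than in each of the other 3; line 3 had 1295 lower calls, the most of any bar on the right.

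Line 1 differed from each of the others most in MGST1, a membrane-bound glutathione transferase. Its level was 10.93 ± 0.17 in line 1 (log2 mean ± SD, n = 3) and 2.73 to 2.98 in the others, all near background, a difference of at least 7.96 ± 0.14 (standard error; 248-fold; limma adjusted p = 9.15e-09). The urothelial membrane protein UPK1B was 33.0-fold higher than in the next line, the interferon-inducible GTPase GBP1 19.8-fold, the sugar nucleotide receptor P2RY14 17.9-fold and the leukocyte adhesion molecule VCAM1 14.2-fold. The actin bundling protein PLS1 was 9.42-fold higher and remained above background in every line, at 11.20 ± 0.23 in line 1. The endothelial lipase LIPG was 7.13-fold higher and GALT, an enzyme of galactose metabolism, 9.03-fold higher. GBP1, P2RY14, VCAM1 and LIPG were near background in each other line. Of the probe sets of a gene, 2 of 3 were called for MGST1 and 3 of 4 for GALT. The uncalled GALT probe set was not higher in line 1 than the mean of the other lines.

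Among genes lower in line 1 than in each other line, the RNA binding protein CELF2 was 14.1-fold lower (5.08 ± 0.72 against 8.89 or more; limma adjusted p = 1.53e-05). The bone morphogenetic protein BMP2, an inducer of bone formation, was 6.59-fold lower, at 5.15 ± 0.16 against 7.87 to 9.98. The vasoconstrictor peptide gene EDN1 was 4.72-fold lower, the kinesin KIF5C 5.20-fold, the cell surface heparan sulphate proteoglycan GPC3 3.63-fold and the basement membrane collagen COL15A1 3.47-fold. EDN1 and KIF5C were near background in line 1, and 2 of 6 probe sets were called for CELF2, 1 of 2 for GPC3 and 2 of 4 for COL15A1. In all, 492 probe sets were higher and 147 lower in line 1 than in each of lines 2, 3 and 4. By the naming rule itself, the 12 genes named per direction differed in all 3 arrays from all 9 arrays of the other lines. Their limma adjusted p-values ran up to 0.0105, that of the corepressor gene GSE1. With the mean of a gene's probe sets in place of 1 probe set, CCNI, GSE1 and COL15A1 no longer met the difference minimum, at -0.44, -0.73 and -0.77 on the log2 scale.

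Line 2 was set apart by MATN2, a matrix adaptor protein of the matrilin family, at 9.37 ± 0.04 against 2.58 to 2.94 in the other lines (log2, n = 3). The difference of 6.44 ± 0.06 (standard error) corresponded to 86.5-fold (limma adjusted p = 1.71e-10), but it was called in 1 of the gene's 3 probe sets. Tissue-nonspecific alkaline phosphatase (ALPL), an enzyme of bone mineralisation, was 27.3-fold higher, at 7.09 ± 0.25, whereas its probe set with the higher mean over all arrays read 6.08 ± 0.36 in line 2 against 4.90 to 5.03 in the others. STAT4, a transcription factor of cytokine signalling, was 27.2-fold higher, at 9.34 ± 0.03. The T cell receptor chain gene CD3G read 8.29 ± 0.08 in line 2 and 2.58 to 2.66 elsewhere. The leukocyte actin bundling protein LCP1 was 16.7-fold higher, and its brightest probe set read 9.60 in line 2 and 6.24 in line 3. The guanine nucleotide exchange factor RASGRP2 was 20.2-fold higher. The collagen-binding integrin subunit ITGA11 read 6.86 ± 0.56 in line 2, and the matrix protein gene ECM2 was 12.3-fold higher. By the probe sets quoted for their folds or levels in line 2, ALPL, STAT4, CD3G, LCP1, RASGRP2 and ITGA11 were near background in each other line. Of the probe sets, 2 of 4 were called for RASGRP2, 2 of 3 for ITGA11 and 2 of 3 for ECM2. Uncalled probe sets of RASGRP2 and ITGA11 included some that were not higher in line 2 than the mean of the other lines.

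Lower in line 2 were the ubiquitin ligase TRIM13, by 27.9-fold (4.80 ± 0.75 against 9.60 to 11.96; limma adjusted p = 1.19e-06), and the calmodulin-dependent phosphodiesterase PDE1A, by 6.56-fold. DUSP5, a phosphatase of the nuclear kinase ERK, was 4.98-fold lower, the DNA glycosylase NEIL2 5.25-fold lower and TIPARP, a target of the aryl hydrocarbon receptor, 4.32-fold lower. The endoplasmic reticulum membrane protein CKAP4 was 3.57-fold lower, at 8.73 ± 0.09 against 10.57 to 12.55. There were 505 probe sets higher and 167 lower in line 2 than in each other line, whereas with no minimum difference 3208 were higher and 3255 lower. The 24 named genes had limma adjusted p-values up to 0.000367, that of the transcription factor gene ETV1. OCIAD1 was 5.71-fold lower by 1 of its 3 probe sets, and over the mean of its probe sets the difference was -0.52. For TRIM13 2 of 3 probe sets were called, for PDE1A 1 of 2 and for NEIL2 1 of 3, and PDE1A and OCIAD1 were near background in line 2.

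Line 3 had the largest number of lower calls. SERPINB2, an inhibitor of plasminogen activators, read 11.05 ± 0.12 in line 3 (log2, n = 3) and was near background in the other lines, a difference of 8.12 ± 0.09 (standard error; 279-fold; limma adjusted p = 1.81e-10). UCHL1 was 159-fold higher, the protease-activated receptor F2RL2 70.3-fold, the transmembrane protein TMEFF2 62.5-fold and the protease inhibitor TFPI2 57.9-fold. Podoplanin (PDPN), a mucin-like glycoprotein of lymphatic endothelium and some fibroblasts, was 43.1-fold higher in line 3, with all 4 of its probe sets called. Fibrillin 2 (FBN2), a component of microfibrils, was 22.6-fold higher, the urate transporter SLC2A9 20.7-fold and the mechanosensitive channel PIEZO2 17.8-fold. F2RL2, PDPN, FBN2, SLC2A9 and PIEZO2 were near background in each other line, and 1 of 2 probe sets was called for FBN2 and 2 of 4 for PIEZO2.

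Among genes lower in line 3, the secreted protein gene ECRG4 stood at 2.73 ± 0.13 against 9.75 to 12.07, 129-fold lower (limma adjusted p = 3.47e-09). The fatty acid elongation enzyme HACD4 was 69.4-fold lower, FILIP1L 47.0-fold and the cytidine triphosphate synthase CTPS2 31.7-fold. Prominin 1 (PROM1), the stem cell surface antigen CD133, was 30.0-fold lower, and the unconventional cyclin CCNG2 22.8-fold lower. ANKRD1, a target of the Hippo pathway effector YAP, was 15.8-fold lower, at 3.70 ± 0.41 against 7.68 to 11.63, and the collagen-binding integrin subunit ITGA10 14.6-fold lower. All 8 of these genes were near background in line 3, and 2 of 4 probe sets were called for CTPS2. Its other probe sets were not lower in line 3 than the mean of the other lines. In line 3, 484 probe sets were higher and 1295 lower than in each other line, whereas with no minimum difference 5963 were higher and 4599 lower. The 24 named genes had limma adjusted p-values up to 5.14e-05, that of KLHL23.

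In line 4, the transcriptional regulators ID1 and ID3 were 6.32-fold (13.59 ± 0.07 against 8.89 to 10.93; limma adjusted p = 8.46e-09) and 6.24-fold higher. The bone morphogenetic protein BMP6 was 6.44-fold higher and the inhibitory SMAD6 6.86-fold higher, SMAD6 by 1 of 3 probe sets. The neuronal pentraxin NPTX2 was 13.4-fold higher, at 9.25 ± 0.43 (log2, n = 3), with a standard error of the difference of 0.18. The glutamate transporter SLC1A1 was 6.51-fold higher and the mesenchymal transcription factor TWIST1 4.98-fold higher, at 6.37 ± 0.97. SMAD6 and TWIST1 were near background in each other line.

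The fatty acid binding protein FABP3 was 577-fold lower in line 4, at 3.38 ± 1.62 against 12.56 to 13.12, with a standard error of 0.63 and limma adjusted p = 3.83e-06. Without replicate 1 of line 4 the difference was -10.10 in place of -9.17 (log2), or 1100-fold. The amino acid transporter SLC38A5 was 153-fold lower, by 1 of 2 probe sets, and SRPX 16.4-fold lower by all 3. The other SLC38A5 probe set was not lower in line 4 than the mean of the other lines. INSIG1 was 11.3-fold lower, the cytochrome CYP1B1 8.15-fold, the growth cone protein GAP43 7.48-fold and GUCY1B1, a subunit of the nitric oxide receptor, 6.84-fold. FABP3, SLC38A5, SRPX, CYP1B1 and GUCY1B1 were near background in line 4, and 1 of 2 probe sets was called for GAP43 and for GUCY1B1. There were 224 probe sets higher and 348 lower in line 4 than in each other line, whereas with no minimum difference 2096 were higher and 2018 lower. The 24 named genes of line 4 had limma adjusted p-values up to 0.00314, that of KIRREL1. Over the mean of a gene's probe sets, SMAD6 (0.83), SLC37A1 (0.60) and JAZF1, which came just short of the minimum, were no longer called.

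**Figure D3:**
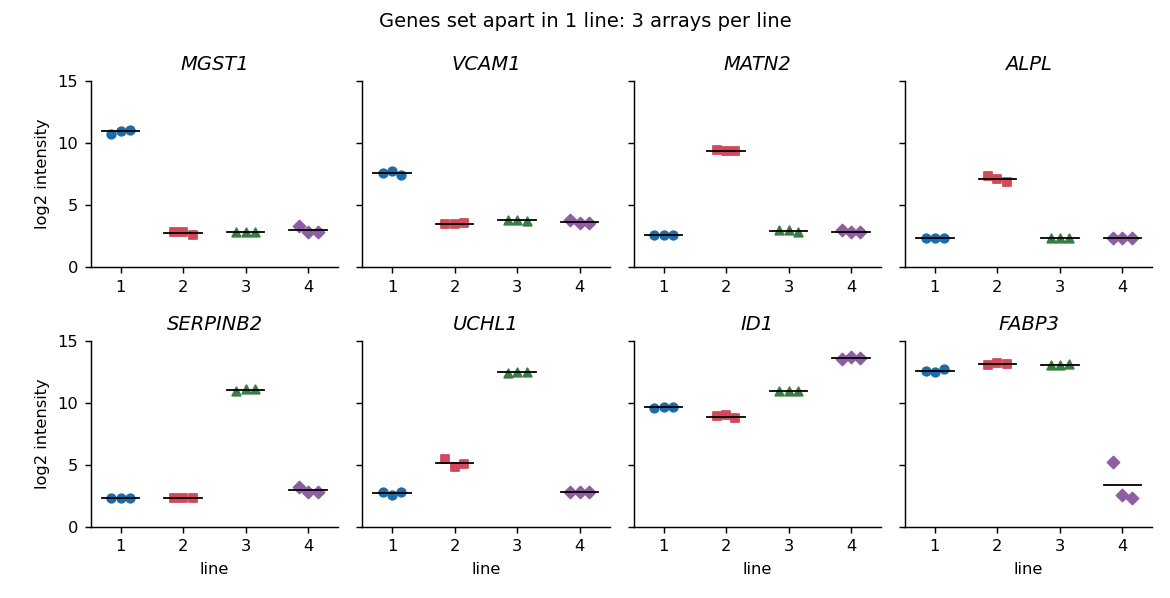
Log2 intensity (vertical axis) on each of the 3 arrays of lines 1 to 4 (horizontal axis) for 8 of the named genes, with 1 point per array and a bar at the line mean. MGST1 and VCAM1 were highest in line 1, MATN2 and ALPL in line 2, SERPINB2 and UCHL1 in line 3 and ID1 in line 4, while FABP3 was lowest in line 4.

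Lines 1 and 2 were measured at the same control level. THBS2 was 2223-fold higher in line 2 (13.12 ± 0.04 in line 2 and near background in line 1 by the probe set with the largest difference in this pair, log2, n = 3), the calcium channel gene TRPV2 286-fold, asporin (ASPN), a small leucine-rich proteoglycan, 211-fold and HAPLN1, which links hyaluronan to proteoglycans, 191-fold. Lower in line 2 were DOCK8, an exchange factor of haematopoietic cells, by 24.7-fold, the ubiquitin protease USP25 by 23.8-fold, thrombospondin 3 (THBS3) by 20.5-fold and KAZALD1 by 19.4-fold. The standard errors of these 8 differences ran from 0.02 to 0.44, and the largest limma adjusted p was 6.93e-06. For DOCK8 2 of 6 probe sets were called and for USP25 3 of 4, and the lower line was near background for all but THBS3. In all, 1341 probe sets were higher and 1506 lower in line 2 (2847 of 42924, the fewest of any pair), whereas with a minimum log2 difference of 2 there were 361 higher and 252 lower.

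Lines 3 and 4, which shared the other control level, differed in several of the same genes. IGF2BP1, an oncofetal RNA binding protein, was 288-fold higher in line 4 (13.01 ± 0.12 against 4.84 ± 0.30; limma adjusted p = 1.67e-09), SUSD5 125-fold, CMTM8 83.3-fold and THBS3 49.9-fold. THBS2 was 3471-fold lower in line 4, the metalloreductase STEAP2 411-fold, TRPV2 322-fold and the histamine-degrading enzyme HNMT 159.7-fold. With the exception of IGF2BP1 and THBS3, these genes were near background in the lower line of the pair. In this pair 2416 probe sets were higher and 1443 lower in line 4, 3859 in all. With no minimum difference 7883 were higher and 9124 lower, and with a minimum of 2 on the log2 scale 468 and 478.

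Between lines 1 and 3, THBS2 (3688-fold), STEAP2 (389.9-fold), TRPV2 (322-fold) and the collagen VI chain gene COL6A3 (197-fold) were higher in line 3. The bile acid receptor NR1H4 was 179-fold lower in line 3, the interferon-inducible IFI44 132-fold, IGF2BP1 127-fold and CMTM8 78.7-fold, with limma adjusted p-values of 1.06e-07 or less. NR1H4 and IFI44 were also lower in line 4 than in lines 1 and 2. Apart from IGF2BP1, each of these genes was near background in the lower line of the pair. This pair had the most calls, with 3199 probe sets higher and 4979 lower in line 3 (8178), whereas with no minimum difference 18054 were higher and 10119 lower. The median difference over all probe sets was 0.15 on the log2 scale, against 0.02 after the arrays were normalized again to a single distribution.

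Between lines 2 and 3, the prostaglandin receptor PTGER2 was 37.1-fold higher in line 3 (8.38 ± 0.17 against 3.17 ± 0.50), ZC3H13 30.4-fold, the AP-1 subunit FOSL1 28.1-fold and ZNFX1 24.0-fold, though 1 of the 4 ZNFX1 probe sets was called the opposite way. ZC3H13 was called by 2 of 3 probe sets, MYO5B by 2 of 5 and MAP3K1 by 2 of 3. NR1H4 was 68.7-fold lower, the motor protein MYO5B 57.2-fold, IFI44 48.6-fold and the kinase MAP3K1 33.9-fold. In line 4, ZC3H13, FOSL1 and ZNFX1 were also higher than in lines 1 and 2, and NR1H4, IFI44 and MAP3K1 lower. These genes thus followed the control levels. Except for ZNFX1, the lower line of the pair was near background. The largest limma adjusted p among the 8 was 2.18e-05. There were 2888 probe sets higher and 4380 lower in line 3 (7268), whereas with no minimum difference 19476 were higher and 10091 lower. The median difference over all probe sets was 0.19, and 0.03 after the second normalization.

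Between lines 1 and 4, ZCCHC10 (21.0-fold), QSOX2, an enzyme that forms disulphide bonds (19.3-fold), the DNA binding protein ARID3A (15.5-fold) and TSPAN18 (14.3-fold) were higher in line 4. The chromatin remodeller SMARCA1 was 38.9-fold lower, IFI35 30.1-fold, the metabolic hormone gene FGF21 27.9-fold and HSD17B7, an enzyme of cholesterol synthesis, 25.2-fold (limma adjusted p = 6.87e-07). SMARCA1, IFI35, FGF21 and HSD17B7 were likewise lower in line 3 than in lines 1 and 2, and ZCCHC10, QSOX2, ARID3A and TSPAN18 were likewise higher there. Every gene named for this pair thus followed the control levels, where batch and line cannot be told apart. For all but QSOX2, FGF21 and HSD17B7, the lower line of the pair was near background. In this pair 1847 probe sets were higher and 2948 lower in line 4 (4795), whereas with no minimum difference 11676 were higher and 8659 lower.

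Between lines 2 and 4, the nuclear receptor HNF4G (39.0-fold), IGF2BP1 (36.6-fold), the EGF receptor ligand EREG (34.2-fold) and ZC3H13 (20.0-fold) were higher in line 4. THBS2 (2011-fold), TRPV2 (286-fold), HAPLN1 (181-fold) and the Wnt antagonist SFRP2 (167-fold) were lower, with limma adjusted p-values of 2.35e-08 or less. ZC3H13 was also higher in line 3 than in lines 1 and 2. By the probe sets quoted, all named genes of this pair but IGF2BP1 and EREG were near background in its lower line. The brightest SFRP2 probe set, given with the Wnt list below, was above background in line 4. There were 2853 probe sets higher and 3743 lower in line 4 (6596), whereas with no minimum difference 16074 were higher and 9231 lower.

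The gene lists were tested in each line against the mean of the others with limma's camera, 30 lists in 4 lines, and 12 of the 120 tests passed an adjusted p of 0.05. With an inter-gene correlation estimated from the data, 4 of them passed: the collagen and matrix list in lines 2 and 4 and the cholesterol list in lines 1 and 4. In each list below, the number of genes that differed among the lines by the F test adjusted over the list alone equalled the number over all probe sets. Each gene was represented by its brightest probe set, which for MATN2, ALPL, LCP1, UCHL1, COL6A3, IFI44, SFRP2 and, in the pair of lines 1 and 2, THBS2 was not the one quoted for its fold above. A list's median, mean and test direction differed in sign in 33 of the 120 tests and in 0 of the 12 that passed. Members named below that were not set apart in a line, outside the lists of surface markers, support factors and osteoblast, adipocyte and cartilage genes, were chosen after the values were seen.

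Of the mesenchymal stromal surface markers, 11 of 20 differed among the lines. THY1 (CD90) read 10.82, 10.97, 9.77 and 10.35 in lines 1 to 4 (log2), CD44 10.80 to 11.51 and the tetraspanin CD9 13.85 to 14.20, and CD44 and CD9 did not meet the criteria of the F test. The TGF-beta co-receptor ENG (CD105) was highest in line 3 at 10.19 ± 0.09 and lowest in line 2 at 7.85 ± 0.13 (n = 3), the aminopeptidase ANPEP (CD13) was highest in line 3 at 9.51 ± 0.14, and ALCAM (CD166) was highest in line 2 at 11.85 ± 0.10. The growth factor receptor PDGFRB was lower in line 4 (5.80 ± 0.40) than in each other line (limma adjusted p = 9.77e-06), and VCAM1 was higher in line 1. NGFR and the leptin receptor LEPR were near background in every line. For the list as a whole, the smallest camera adjusted p was 0.317.

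Of the leukocyte and haematopoietic markers, 1 of 20 differed, LCP1, and 10 were near background in every line. The myeloid transcription factor SPI1 read 2.58 in each line, while CD34 read 5.63 to 5.84. Of the endothelial markers, 4 of 15 differed, among them the VEGF receptor FLT1, highest in line 4 at 12.38 ± 0.05. PECAM1 was among the 4 that were near background in every line, while the VEGF receptor KDR read 7.20 to 8.42 and the transcription factor ERG 6.98 to 9.53. The epithelial list had 3 of 9 genes that differed: EPCAM was highest in line 2 at 7.21 ± 0.04, the tight junction gene OCLN was lowest in line 3 at 2.58, and ESRP1 spanned 4.80-fold, and 4 were near background in every line. The skeletal muscle list had 3 of 11 that differed and 7 near background in every line, MYOD1 and PAX7 among them, while the actin ACTA1 read 11.61 to 12.73. In camera, the smallest adjusted p-values of these lists were 0.172, 0.238, 0.428 and 0.25, in that order.

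In the smooth muscle and pericyte list 5 of 15 genes differed. Calponin (CNN1) was highest in line 3 (12.81 ± 0.06) and lowest in line 1 (5.69 ± 0.32), a 139-fold range (F test adjusted p = 7.21e-09, limma), and the smooth muscle actin ACTG2 was highest in line 3 at 12.12 ± 0.06. The list's smallest adjusted p against the mean of the other lines was 0.0523, while line 2 over line 1, within a control level, gave a median of 0.37 and adjusted p = 0.00953 (adjusted p = 0.273 with an estimated correlation). Of the neural and glial markers, 5 of 12 differed and the list was higher in line 3 (median difference 0.63; adjusted p = 0.0374; adjusted p = 0.258 with an estimated correlation). Without replicate 2 of line 3 that adjusted p was 0.0512. Within the control level, line 4 minus line 3 gave -0.62 for the list (adjusted p = 0.0139, and adjusted p = 0.168 with an estimated correlation). UCHL1 and the adhesion molecule NCAM1 (8.10 ± 0.03) were higher in line 3, whereas GAP43 was highest in line 2 (13.00 ± 0.10) and lowest in line 4, and SOX10 read 2.58 in each line.

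In the osteoblast list 9 of 14 genes differed: BMP2 was lowest in line 1, the parathyroid hormone receptor PTH1R was highest in line 2 (6.03 ± 0.11), and the homeobox gene MSX2 was lowest in line 4 (7.36 ± 0.65). The matrix protein SPARC, at 14.56 to 14.83, did not meet the criteria, nor did the regulator RUNX2, at 6.49 to 7.23. In the adipocyte list 4 of 13 differed, including the desaturase SCD, lowest in line 4 (12.95 ± 0.12), and the regulator PPARG, at 5.59 ± 0.29 in line 1 and 3.24 ± 0.38, near background, in line 2. In the cartilage list 3 of 15 differed: HAPLN1 was highest in line 2 (10.89 ± 0.08), aggrecan (ACAN), though near background in every line, was highest in line 3 (4.75 ± 0.20), and lubricin (PRG4) spanned 4.10-fold. SOX9 was near background in every line. The osteoblast, adipocyte and cartilage lists had smallest camera adjusted p-values of 0.362, 0.243 and 0.351.

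Among the haematopoietic support factors, which bear on the intended use of stromal lines, 9 of 22 differed and 8 were near background in every line. The chemokine CXCL12, which retains blood stem cells in the marrow, was highest in line 3 (9.67 ± 0.06), read 6.97 ± 0.17 in line 2 and was near background in lines 1 and 4, a 108-fold range (F test adjusted p = 1.87e-08, limma). Stem cell factor (KITLG) was highest in line 3 (10.76 ± 0.04) and lowest in line 1 (7.02 ± 0.40). The Notch ligand JAG1 was lowest in line 4 (5.39 ± 0.15), angiopoietin 1 (ANGPT1) was 9.02 and 8.71 in lines 1 and 2 and 7.25 and 7.01 in lines 3 and 4, and TGFB2 was highest in line 2 (11.12 ± 0.01). Interleukin 6 (IL6) and LIF were near background in every line. The list's smallest adjusted p against the mean of the other lines was 0.252, and within the control level line 4 minus line 3 gave -0.25 (adjusted p = 0.0416, and adjusted p = 0.292 with an estimated correlation).

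Of 19 inflammatory cytokines and chemokines 8 differed, and 9 were near background in every line. The monocyte attractant CCL2 was highest in line 3 (11.36 ± 0.11) and lowest in line 4 (5.76 ± 0.63), while the neutrophil attractant CXCL8 was lowest in line 3 (5.27 ± 1.02) and read 10.55 ± 0.13 in line 4. The adhesion molecule ICAM1 was highest in line 4 (13.21 ± 0.05) and the macrophage growth factor IL34 highest in line 1 (11.01 ± 0.05). Of 17 immune modulation factors 6 differed, among them PTGS2, an enzyme of prostaglandin synthesis, at 6.73 ± 0.14 and 7.17 ± 0.52 in lines 3 and 4 and near background at 4.69 in lines 1 and 2. The hormone STC1 was highest in line 4 (5.98 ± 0.09), and IDO1 read 5.57 to 5.96. For the inflammatory and the immune modulation list, the smallest camera adjusted p-values were 0.107 and 0.388.

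Of 20 interferon response genes 12 differed among the lines, with 2 higher in line 1, 1 higher in line 2, 1 higher and 2 lower in line 3, and 1 lower in line 4 than in each other line. The ubiquitin-like modifier ISG15 was 11.11 ± 0.16 and 11.44 ± 0.59 in lines 1 and 2 and 7.87 ± 0.19 and 6.91 ± 0.30 in lines 3 and 4 (log2, n = 3), and the transcription factor subunit IRF9 was 9.47, 9.82, 7.71 and 7.59. The antiviral GTPase MX1 was highest in line 2 (9.26 ± 0.83) and the synthetase OAS2 lowest in line 4 (4.22 ± 0.32), while IFI6 was highest in line 3 (9.39 ± 0.43). The list was higher in line 2 (median difference 0.56; camera adjusted p = 0.0141; adjusted p = 0.572 with an estimated correlation) and lower in line 4 (-0.28; adjusted p = 0.0217; adjusted p = 0.572 with an estimated correlation). Within the control levels neither shift passed: line 2 minus line 1 gave 0.09 (adjusted p = 0.563) and line 4 minus line 3 gave -0.05 (adjusted p = 0.986). The bioB controls differed by 5.34-fold and the actin 3' minus 5' signal by -3.58 (log2) between lines 3 and 4 and lines 1 and 2, the pairs that differed in ISG15 and IRF9. Of 20 antigen presentation genes 5 differed: the class I gene DLA-64 was 7.21 and 7.03 in lines 2 and 3 and near background in lines 1 and 4, while the class II genes DLA-DRA and DLA-DQA1 were near background throughout (smallest camera adjusted p 0.441).

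Of the cell cycle genes, 10 of 25 differed among the lines, and 0 were higher or lower in any line than in each other line. The mitotic kinase PLK1 was 12.99 ± 0.24 in line 4 and 10.55 ± 0.07 in line 2, and cyclin A2 (CCNA2) 12.41 ± 0.11 and 10.95 ± 0.05. The list was higher in line 4 (median difference 0.27; camera adjusted p = 0.00135; adjusted p = 0.0734 with an estimated correlation) and lower in line 2 (-0.22; adjusted p = 0.0475; adjusted p = 0.27 with an estimated correlation). The line 2 shift lost its call, with adjusted p-values of 0.0517 to 0.0716, without replicate 2 of line 1, replicate 2 or 3 of line 2, replicate 1, 2 or 3 of line 3, or replicate 3 of line 4. Within the control levels the medians were -0.07 in line 2 minus line 1 (adjusted p = 0.44) and 0.19 in line 4 minus line 3 (adjusted p = 0.107), and neither passed. Of 19 p53 target genes 8 differed, including the cell cycle inhibitor CDKN1A, lowest at 10.67 ± 0.08 in line 2, and the kinase PLK2, lowest in line 3 (9.05 ± 0.05). The membrane protein gene PERP was highest in line 2 (8.87 ± 0.01) and lowest in line 4 (5.34 ± 0.41). In the list of cyclin-dependent kinase inhibitors and the RB family 7 of 14 differed: cyclin D2 (CCND2) was lowest in line 3 (8.52 ± 0.18) and RBL1 was 7.17 and 7.31 in lines 1 and 2 and 5.32 and 5.26 in lines 3 and 4. Both these lists had a smallest camera adjusted p of 0.339.

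Among the collagens and other matrix proteins, 25 of 31 differed. In line 1, 2 were lower than in each other line, in line 2, 5 were higher, in line 3, 3 were higher and 2 lower, and in line 4, 5 were lower. Line 2 had the highest levels of collagen XII (COL12A1, 13.91 ± 0.05), collagen IV alpha 1 (COL4A1, 12.43 ± 0.04), the proteoglycan versican (VCAN, 12.78 ± 0.13), osteoglycin (OGN, 12.74 ± 0.05) and nidogen (NID1, 7.48 ± 0.16), each higher than in every other line. Line 4 had the lowest decorin (DCN, 12.35 ± 0.19), lumican (LUM, 13.27 ± 0.06) and fibulin 2 (FBLN2, 9.29 ± 0.05). Periostin (POSTN) was 9.99 ± 0.09 and 9.82 ± 0.09 in lines 2 and 3 and near background in lines 1 and 4. The main fibrillar collagen COL1A1 was 15.67 to 16.18 in every line. The list was higher in line 2 (median difference 0.69; camera adjusted p = 1.41e-10; adjusted p = 0.0132 with an estimated correlation), lower in line 4 (-1.01; adjusted p = 3.85e-10; adjusted p = 0.0132 with an estimated correlation) and lower in line 1 (-0.53; adjusted p = 0.00135; adjusted p = 0.109 with an estimated correlation). Within the control levels, line 2 minus line 1 gave 0.92 (adjusted p = 2.97e-14; 0.00374 with an estimated correlation) and line 4 minus line 3 gave -0.98 (adjusted p = 1.70e-07; 0.0194 with an estimated correlation).

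**Figure D4:**
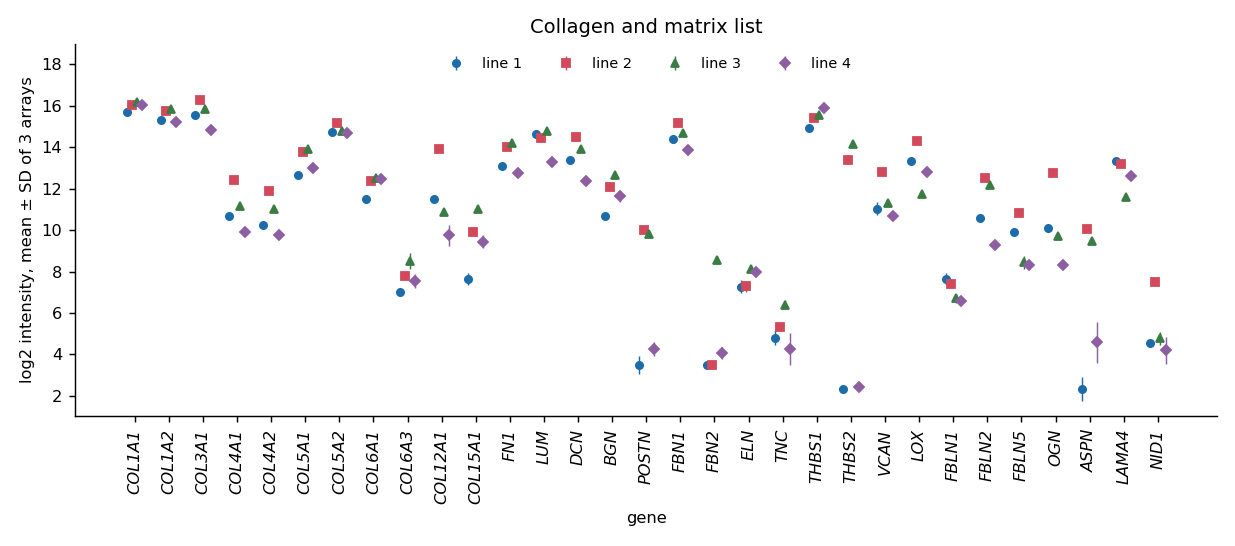
Log2 intensity (vertical axis, mean ± SD of 3 arrays) of the 31 measured collagen and matrix genes (horizontal axis) in lines 1 to 4, 1 marker per line. THBS2 stood at 13.38 and 14.17 in lines 2 and 3 and at 2.32 and 2.41 in lines 1 and 4.

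In the list of matrix proteases and inhibitors 11 of 17 genes differed. Cathepsin K (CTSK), a collagen-degrading protease, was highest in line 2 (13.06 ± 0.03) and lowest in line 4 (8.44 ± 0.19), the gelatinase MMP2 was 9.90 and 10.33 in lines 2 and 3 and 8.14 and 8.43 in lines 1 and 4, and the protease inhibitor SERPINE2 was highest in line 3 (13.86 ± 0.02). Stromelysin (MMP3) was near background in lines 1 to 3 and 4.80 ± 0.87 in line 4. The list's smallest camera adjusted p was 0.363.

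Of 15 insulin-like growth factor genes 6 differed: IGF2BP1 was highest in line 4 and lowest in line 3, and the binding protein gene IGFBP6 was highest in line 2 (11.78 ± 0.20), while IGF1, IGF2 and IGFBP3 were near background in every line. Of 27 Wnt pathway genes 7 differed, with the antagonists SFRP2 lowest in line 4 (8.69 ± 0.19) and FRZB lowest in line 3 (4.59 ± 0.39) and the ligand WNT5B highest in line 4 (9.77 ± 0.29). Of 21 HOX genes 5 differed: HOXD10 was 9.74 ± 0.21 and 9.02 ± 0.19 in lines 2 and 3 and 6.30 ± 0.10 and 4.75 ± 0.05 in lines 1 and 4, and HOXB4 was 8.65 and 8.88 in lines 1 and 4 and 6.15 and 6.31 in lines 2 and 3. Of 31 limb and skeletal patterning factors 8 differed, including PRRX1, highest in line 3 (12.70 ± 0.03), and TWIST1, and 15 were near background in every line. The 4 lists had smallest camera adjusted p-values of 0.363, 0.243, 0.362 and 0.752.

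Of the 17 measured cholesterol synthesis genes, all of which differed among the lines, 10 were higher in line 1 than in each other line, among them the squalene enzymes SQLE (13.28 ± 0.16) and FDFT1 (12.20 ± 0.18), the late enzymes DHCR7 (10.72 ± 0.20) and EBP (12.20 ± 0.21), and the feedback regulator INSIG1 (12.56 ± 0.13). In line 4, INSIG1 (5.70 ± 0.43) and the pathway's transcription factor SREBF2 (7.35 ± 0.23) were lower than in each other line. The list was higher in line 1 (median difference 1.68; camera adjusted p = 6.43e-11; adjusted p = 0.0192 with an estimated correlation) and lower in line 4 (-1.18; adjusted p = 9.00e-11; adjusted p = 0.0192 with an estimated correlation). Within the control levels, line 2 minus line 1 gave -1.31 (adjusted p = 2.97e-09; 0.0226 with an estimated correlation) and line 4 minus line 3 gave -0.61 (adjusted p = 0.00106; adjusted p = 0.194 with an estimated correlation).

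**Figure D5:**
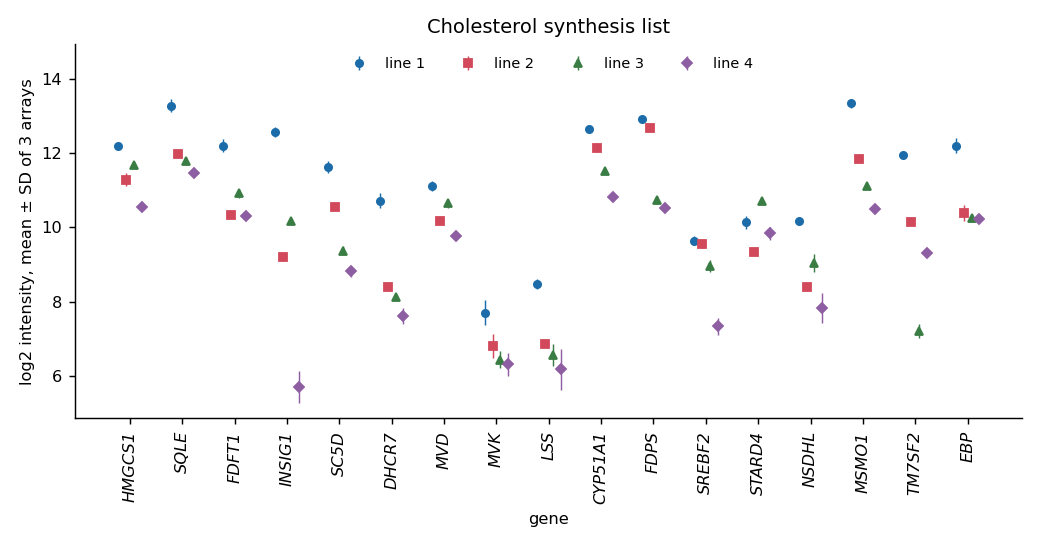
Log2 intensity (vertical axis, mean ± SD of 3 arrays) of the 17 measured cholesterol synthesis genes (horizontal axis) in lines 1 to 4, 1 marker per line. INSIG1 ranged from 5.70 in line 4 to 12.56 in line 1.

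Of 24 glycolysis and hypoxia genes 18 differed among the lines, with 2 higher in line 1, 1 lower in line 2, 1 higher and 2 lower in line 3, and 2 higher in line 4 than in each other line. Lactate dehydrogenase A (LDHA) was 14.51 ± 0.08 in line 2 and 15.67 ± 0.04 in line 4, the glucose transporter SLC2A1 9.40 ± 0.11 and 11.45 ± 0.10, and the phosphofructokinase PFKL 11.06 ± 0.03 and 12.66 ± 0.08. ANKRD37, a hypoxia-inducible gene, was lower in line 2 (8.92 ± 0.22) than in each other line and 8.43-fold higher in line 4 than there, and ANGPTL4, a lipoprotein lipase inhibitor, was highest in line 4 (10.19 ± 0.12). The carbonic anhydrase CA9 and adrenomedullin (ADM), both also induced by hypoxia, were highest in line 3 (7.48 and 13.26). The list's median difference was -0.70 in line 2 (camera adjusted p = 0.00616; adjusted p = 0.496 with an estimated correlation) and 0.54 in line 4 (adjusted p = 0.0138; adjusted p = 0.526 with an estimated correlation). Within the control levels it was -0.64 in line 2 minus line 1 (adjusted p = 0.00152) and 0.54 in line 4 minus line 3 (adjusted p = 0.00769), each with adjusted p = 0.292 with an estimated correlation.

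Of 20 antioxidant genes 6 differed, such as glutathione reductase (GSR), 10.58 ± 0.05 in line 1 and 8.66 ± 0.04 in line 2, and catalase (CAT), 10.92 and 11.27 in lines 1 and 2 and 9.77 and 9.61 in lines 3 and 4. Of 21 immediate early genes 13 differed: FOS was highest in line 1 (10.47 ± 0.23) and lowest in line 3 (7.06 ± 0.26), JUN was highest in line 3 (11.66 ± 0.17) and lowest in line 1 (7.80 ± 0.41), and KLF4 was highest in line 2 (13.84 ± 0.03) and lowest in line 4 (9.72 ± 0.01). Of 19 endoplasmic reticulum stress genes 10 differed, with the stress transcription factor DDIT3 lowest in line 4 (8.57 ± 0.02) and the chaperone HYOU1 highest in line 3 (8.81 ± 0.11). Of 22 DNA repair genes 11 differed: the end-binding protein XRCC5 was highest in line 3 (10.36 ± 0.07), and the damage kinase ATM (4.84 ± 0.28) and the nuclease MRE11 (5.68 ± 0.56) were lowest there, while PRKDC was 10.24 and 10.26 in lines 1 and 2 and 8.63 and 8.34 in lines 3 and 4. In the order given, the smallest camera adjusted p-values were 0.362, 0.363, 0.0979 and 0.363.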

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

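All tests of the batch were chosen after the control levels had been seen, whereas the tests on other probe sets and on a second normalization were written beforehand. The bacterial and phage control probe sets, which the comparisons between lines do not use, carried a signal that separated the arrays into a pair of blocks, with lines 3 and 4 over lines 1 and 2 by 5.34-fold for bioB, 4.21-fold for bioC, 3.17-fold for bioD and 2.06-fold for cre. The 3' minus 5' signal of the canine beta-actin control differed by -3.58 (log2) between the same blocks, while that of the canine GAPDH control differed by -0.30 and that of another GAPDH pair by 0.06. A second pair of actin control probe sets gave smaller excesses of the 3' end, 0.84, 0.38, 0.24 and 0.19 in lines 1 to 4, and the 75th percentile of the intensities was 644 to 685 on the arrays of lines 1 and 2 and 528 to 612 on those of lines 3 and 4.

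The same blocks appeared in the genes, where 655 probe sets were higher and 1198 lower in both lines 3 and 4 than in both lines 1 and 2. The tables argue against scattered shifts of single probe sets as the whole cause, since the brightest other probe set of the same gene moved the same way in 85.7% of genes (669 of 781, exact 95% interval 83.0 to 88.0). They also argue against signal-dependent shifts of the kind a second normalization removes as the whole cause. After it, 83.3% of the probe sets were still called (80.8 to 84.1% with any array left out). The second normalization acted on summarised values, so it could not test the background correction made before them. A processing batch remains open, because 0 lines had arrays at both control levels, and for these probe sets batch and line cannot be told apart. A difference between the cell lines themselves stays open as well and was not tested.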

How the results depend on the processing

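The fits on contrasts within a control level were chosen only after the control split was seen, and all other alternatives were planned. In this part, counts are given in the order of the F test, the pairs 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4, and then higher and lower in lines 1, 2, 3 and 4, and the reported counts in that order were 12824; 2847, 8178, 4795, 7268, 6596 and 3859; and 492 and 147, 505 and 167, 484 and 1295, and 224 and 348. They stayed within 1.5 times of these under median centring, a second normalization, filters at means of 5 and 7, a floor of 4, a trend and robust model, array weights, an adjusted p under 0.01 and each array left out. The pair counts also did so with pairs fitted alone, a setting that was run for them only. Without a minimum difference the counts were 32940; 13787, 28173, 20335, 29567, 25305 and 17007; and 2839 and 1879, 3208 and 3255, 5963 and 4599, and 2096 and 2018. With a minimum log2 difference of 2 they were 3552; 613, 2242, 743, 1586, 1450 and 946; and 68 and 16, 99 and 10, 120 and 215, and 33 and 80. Both follow from the changed threshold. Without a minimum, the excess of 1 direction over the other reversed in lines 2, 3 and 4 and in every pair but 1 and 2, and with a minimum of 2 it reversed in the pairs 1 and 2 and 3 and 4. Without probe sets named _x_at or _s_at, where fewer probe sets were tested, they were 7803; 1793, 4888, 2851, 4360, 4013 and 2357; and 302 and 84, 313 and 109, 322 and 699, and 140 and 250. With 1 probe set per gene, again with fewer tested, they were 4822; 1112, 3105, 1818, 2600, 2462 and 1531; and 193 and 63, 180 and 65, 197 and 514, and 96 and 128. The F test over the contrasts within a control level, which uses fewer contrasts, called 5305 probe sets. Of the 120 tests of a list in a line, 12 were reported as passed, 4 passed with an estimated correlation, and 101 with fry. Fry asks another question, whether the genes of a list shift in a shared direction, without setting them against other genes. With a second normalization the median difference of all probe sets fell from 0.15 to 0.02 in line 3 minus line 1 and from 0.19 to 0.03 in line 3 minus line 2.

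With the replicate number as a replicate block, the pair counts were 2835, 8165, 4777, 7262, 6581 and 3838, and no named gene or shifted list changed its call. The numbers share nothing in the labels, and the deviations of arrays with the same number in different lines had a mean correlation of 0.004 (-0.109 to 0.131), so they do not pair the arrays. Of the 96 genes named for a line, 89 kept their call with the mean of a gene's probe sets and 7 did not, and the cause was not tested; all 48 results named for a pair kept theirs. With each array left out in turn, 136 of 144 list results kept their call, and the other 8 concerned the cell cycle list in line 2 and the neural list in line 3; the cause was not tested. No named gene or list turned its direction. Signal near background limits what these arrays can show: 36.4% of the probe sets were there in every line.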

Other observations

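The genes, the grouping of lines 2 and 3, the batch tests, the matrix test and the check for intact lines in this part were chosen only after the values were seen, whereas the tests on other probe sets, on a second normalization and on other groupings of the arrays were written beforehand. Lines 2 and 3 shared a set of high genes that were low in lines 1 and 4. Besides THBS2 and TRPV2, the metalloreductases STEAP2 and STEAP1 were at least 139-fold and 45.5-fold higher in lines 2 and 3 than in lines 1 and 4, COL6A3 134-fold, the protease inhibitor SPINK5 87.1-fold (10.55 ± 0.14 and 10.08 ± 0.11 against 3.64 ± 0.31 and 3.49 ± 0.19, log2, n = 3), the angiotensin-cleaving aminopeptidase ENPEP 62.0-fold and POSTN 46.8-fold. The survival gene BCL2A1 was 43.2-fold higher and the sialyltransferase ST6GAL2 39.9-fold higher.

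Higher in lines 1 and 4 than in lines 2 and 3 were IGF2BP1, by 16.2-fold, THBS3, by 14.1-fold, the junction protein and virus receptor CXADR, by 13.4-fold (11.90 ± 0.32 and 11.80 ± 0.10 against 8.00 ± 0.45 and 8.06 ± 0.14), the matrix proteoglycan OPTC, by 11.6-fold, and ANKRD1, by 10.1-fold. Among the gene lists, 4 passed camera for lines 2 and 3 over lines 1 and 4. The collagen and matrix list had a median difference of 1.15 (camera adjusted p = 3.32e-12), the smooth muscle and pericyte list 0.15 (adjusted p = 0.00458; adjusted p = 0.2 with an estimated correlation), the neural and glial list 0.33 (adjusted p = 0.0278; adjusted p = 0.2 with an estimated correlation) and the glycolysis and hypoxia list -0.53 (adjusted p = 0.00401; adjusted p = 0.328 with an estimated correlation).

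In all, 693 probe sets separated lines 2 and 3 from lines 1 and 4, 375 of them higher in lines 2 and 3 and 318 lower. The tables argue against a batch along the control levels as the whole cause, because this grouping takes 1 line from each level. The other grouping that does so held 12 probe sets, against 677 to 695 in this one with any array left out. The comparison cannot address a processing step that divided lines 2 and 3 from lines 1 and 4. The way of lysis, for example, is not given for each array. The tables also argue against shifts of single probe sets, because the brightest other probe set of the gene moved the same way in 99.6% of genes (230 of 231, exact 95% interval 97.6 to 99.99). The collagen and matrix list moved with the grouping (camera adjusted p = 0.00349 with an estimated correlation), so a shared matrix programme may be part of it, as a hypothesis found and tested on the same arrays. What lines 2 and 3 have in common, such as a donor or a cell state, was not tested.

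More probe sets were lower than higher in line 3, 72.8% of those set apart there (1295 lower, 484 higher), but with no minimum difference the excess reversed (4599 lower, 5963 higher). The brightest other probe set of the gene moved the same way in 92.9% of genes (632 of 680; exact 95% interval 90.8 to 94.8), which argues against shifts of single probe sets. Within the control level shared with line 4, 62.6% of calls were lower in line 3 (60.3 to 63.2% with any array left out), but 49.5% were with a minimum log2 difference of 2 and 46.4% with none, so a processing batch stays open. After the arrays were normalized again the share of lower calls was 65.6% (64.9 to 66.7%), so signal-dependent normalization may account for part of the excess and its share cannot be told apart from a difference of the line.

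Other groupings of the arrays were counted as a test of chance. Of 100 groupings of the 12 arrays into 4 groups of 3, the real one included, 1 gave as many probe sets by the F test (12824 in the real grouping, 5606 at most in another). A random grouping of the arrays is thus an unlikely source of that count. The count cannot tell a difference between the lines from processing shared by the arrays of a line. For the 120 tests of a list in a line 4 gave as many that passed (12 against at most 16, with a median of 6 in the others). The grouping with 16 had 0 probe sets by the F test, so tests at the preset correlation also passed where no probe set was called. Regrouped arrays can still carry part of the differences between lines. Chance is not treated as excluded for a single list. For probe sets higher in a line than in each other line, with 504 the highest of another grouping in any of its groups, 2 groupings reached the count of line 1 (492), 1 that of line 2 (505), 2 that of line 3 (484) and 14 that of line 4 (224). For lower probe sets, with 1443 the highest elsewhere, 12 reached the count of line 1 (147), 9 that of line 2 (167), 3 that of line 3 (1295) and 5 that of line 4 (348). These numbers of groupings decide nothing about chance for a single line. Groupings that kept a real line together reached every count but the higher count of line 2. All 13 other groupings that reached the smallest real count of higher calls, and all 11 for lower calls, kept the arrays of at least 1 line together, and groupings without an intact line gave at most 0. The pairs of lines allow 10 splits each, too few for a share under 0.05: the real counts were 2847, 8178, 4795, 7268, 6596 and 3859 for the pairs 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4, and the highest of another split were 4, 0, 0, 0, 0 and 4, with 1 split in each pair, the real one, reaching the real count.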
